A study of Mus musculus with 10 samples.

How the data were processed

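ChIP-seq had been run on 10 samples of mouse pre-iPSCs: 1 input, 1 IgG and 8 ChIP samples in 4 groups of 2 replicates. The groups were taken from the sample descriptions: Sin3a ChIP in the Sin3a line, FLAG ChIP in the Nanog line, and FLAG and Sin3a ChIP in the Nanog + Sin3a line. Per the submitters' processing notes, the reads were processed on genome build mm9 with FastQC 0.10.1, Bowtie 1.0.0 and SAMtools 0.1.19, with no role or order stated. The peak caller is not given in the sources used here, nor is whether replicates were pooled before peaks were called. The input and IgG samples were not analysed here.

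Each group has 1 deposited peak list without a header. The deposited score of each peak equals 10 times its −log10 q without decimals in 100% of rows, as tested on the values. The deposited fold enrichment is a ratio at the summit of the scaled ChIP pileup over the expected background, with 1 added to each, as the values show. The pileup was scaled by 0.700 and 0.772 for Sin3a in the Sin3a and Nanog + Sin3a lines, and by 0.868 and 0.731 for FLAG in the Nanog and Nanog + Sin3a lines. The deposited −log10 p of the summit equals a Poisson tail at the scaled pileup without decimals, as the values show, and the deposited −log10 q is the authors' adjusted value. These values are the authors' own and were used to describe, rank or filter peaks within a list. No p-value across peaks was computed.

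The coordinates were checked against both builds: the last peak passes the chromosome length of the later build GRCm38 on 8 of 20 chromosomes and that of mm9 on 0, with lengths from GenomeInfoDb 1.38.1. The gene table used here is of GRCm38. Its coordinates were therefore not used, none were converted, and the planned shares of peaks at promoters and counts of gene lists were not run. Coordinates are printed 1-based.

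From fold and −log10 p, the whole number of ChIP fragments over each summit, before scaling, was recovered. Exactly 1 number fitted for at least 99.6% of the peaks of each list. All 4 lists gave the same control depth of 25.9 tags per kb. Total reads per sample are not given in the sources used here, so depth is known only from these fragment numbers, the control depth and the scaling of each list, and duplicates among the fragments cannot be seen.

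A peak counted as overlapping when it shared at least 1 base with a peak of the other list. No peaks of 1 list overlapped each other. Shares carry 95% Wilson intervals, differences of shares Newcombe intervals and fragment numbers exact Poisson intervals. Where the same peaks were scored against 2 lists, the interval of the difference is the normal one for matched shares, chosen after the data were seen. The Newcombe intervals take the peaks of different lists as independent, although many lie at the same sites. All intervals cover counting error only, since peaks are not replicates. Chance overlap was the mean of 1000 rotations of a list within each chromosome. Strength was compared within a list as the ratio of median folds, beside 10000 random sets of peaks. For regions, peaks of the 4 lists were merged by 1 shared base, and for each of 8 classes the 4 regions with the highest mean −log10 q were eligible to be named. Comparisons, alternatives and this rule were fixed before the data were examined, except where the text says otherwise. The alternatives were 50% of the shorter peak or summits within 200 bp as the overlap, a −log10 q of at least 5 or 10, equal numbers of top peaks, regions of all 4 lists left out, and random placement in place of rotation.

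Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The overlap code was tested on simulated data, where it found 3000 of 3000 shared peaks, and on the deposited Sin3a and FLAG lists of the single-transgene lines, where its count differed from bedtools 2.31.1 by 0 peaks. Independent simulated lists gave 0.985 times the rotated overlap. In 15000 simulated peaks, most of them near the calling threshold, 98.0% had 1 fragment number, which equalled the number drawn in 100% of them. An earlier simulation with evenly spread fragment numbers, unlike a peak list, did not return the background level, so the recovery holds for lists in which weak peaks are the commonest.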

Results

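Binding of the transcription factor Nanog and of the co-repressor scaffold protein Sin3a was profiled by ChIP-seq in mouse pre-iPSCs, partly reprogrammed cells derived from female neural stem cells. Nanog is a core pluripotency factor, and Sin3a assembles a complex that carries histone deacetylases. The cells had been stably transfected with transposon vectors, which gave 3 lines: Sin3a with an empty vector (the Sin3a line), FLAG-tagged Nanog with an empty vector (the Nanog line), and FLAG-tagged Nanog with Sin3a (the Nanog + Sin3a line). Sin3a was precipitated in the Sin3a line and in the Nanog + Sin3a line, and FLAG in the Nanog line and in the Nanog + Sin3a line, with 2 replicates for each of these 4 groups. The series further holds 1 input and 1 IgG sample. Each group is represented by 1 deposited peak list that carries no value per replicate, so that no difference below could be set against the spread between replicates. Intervals are 95% intervals over peaks and cover counting error only.

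FLAG-Nanog peaks outnumbered Sin3a peaks in every pairing of the lists. The lists held 38485 FLAG peaks in the Nanog line and 36286 in the Nanog + Sin3a line, against 17168 Sin3a peaks in the Sin3a line and 18231 in the Nanog + Sin3a line. FLAG peaks were narrower, with median widths of 358 and 351 bp, than Sin3a peaks, with median widths of 498 bp in the Sin3a line and 471 bp in the Nanog + Sin3a line. The FLAG peaks covered 17.7 Mb in the Nanog line and 16.0 Mb in the Nanog + Sin3a line, and the Sin3a peaks covered 10.5 and 10.8 Mb. The authors' fold enrichment at the summit had a median of 4.72 and a maximum of 27.3 for Sin3a in the Sin3a line, and a median of 4.75 and a maximum of 42.4 for FLAG in the Nanog line. The number of ChIP fragments over a summit, recovered from the fold and the p-value of each peak, had medians of 46 and 38 for Sin3a in the Sin3a and Nanog + Sin3a lines, and of 33 and 39 for FLAG in the Nanog and Nanog + Sin3a lines. The lists were scaled by 1.43 and 1.30 ChIP tags per control tag for Sin3a, and by 1.15 and 1.37 for FLAG, in the same order of lines.

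Merging the peaks of the 4 lists gave 45707 regions. Regions with FLAG peaks only made up 57.5% of them (26280 regions), regions with both Sin3a and FLAG peaks 37.2% (17018), and regions with Sin3a peaks only 5.27% (2409). The largest class held a FLAG peak in both lines and no Sin3a peak (12306 regions), followed by the class present in all 4 lists (11761 regions, 25.7%, interval 25.3 to 26.1%). Regions found in both lists of the Nanog + Sin3a line and in no other list were few, at 160 (0.350%).

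**Figure D1:**
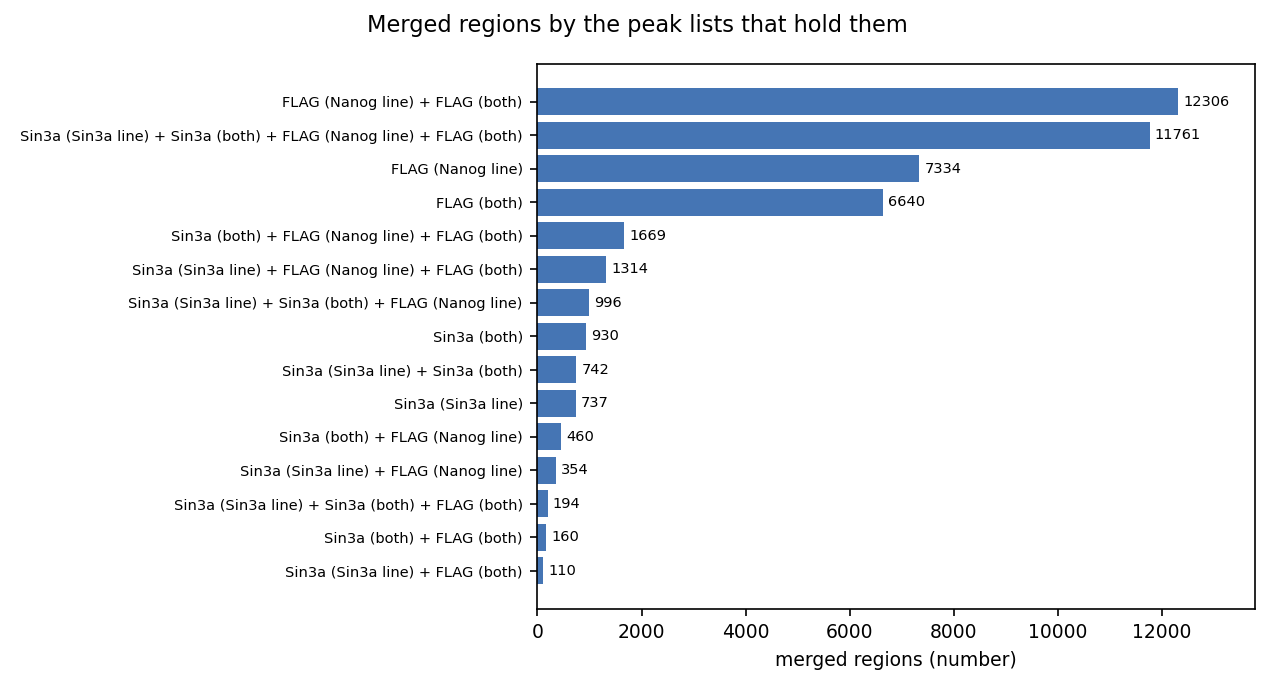
Number of merged regions (horizontal axis) for each of the 15 combinations of peak lists that hold them; each bar is 1 combination, "both" marks the Nanog + Sin3a line, and no error bars apply to these counts. The 2 longest bars are FLAG peaks of both lines without Sin3a (12306) and regions of all 4 lists (11761).

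The regions named here had the highest mean −log10 q of their class, and all coordinates are those of mouse build mm9. Among regions of all 4 lists, the strongest lay on chromosome 19 at 4988902-4989494, where the authors' fold was 27.1 for Sin3a in the Sin3a line and 32.3 in the Nanog + Sin3a line, and 20.8 for FLAG in each line. The summit of this region held 272 Sin3a fragments in the Sin3a line (Poisson interval 241 to 306) and 153 FLAG fragments in the Nanog line (130 to 179). A region on chromosome 7 at 6362677-6363278 had folds of 27.3 and 32.3 in its Sin3a lists, and of 17.2 and 19.1 in its FLAG lists. The remaining named regions of this class had the larger folds in the FLAG lists. On chromosome 5 at 113678318-113678982 the FLAG fold was 41.1 in the Nanog line, and the Sin3a fold 5.29 in the Sin3a line. On chromosome 12 at 77355842-77356786 these folds were 39.0 and 7.25. Each fold is relative to its own list, and fragment numbers are given before scaling. Neither was tested between lists, and neither ranks the proteins against each other.

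FLAG-only regions included peaks among the strongest of their lists. The region on chromosome 17 at 49990270-49991069 had a fold of 36.7 in the Nanog line and 38.2 in the Nanog + Sin3a line. Its summit held 253 and 312 fragments before scaling, in lists scaled by 1.15 and 1.37 ChIP tags per control tag. Further regions of this class lay on chromosome 6 at 98963443-98964394 (folds 28.8 and 26.6), chromosome 11 at 101619807-101620607 (26.6 and 38.1) and chromosome 12 at 113176627-113177654 (28.8 and 27.3). The Sin3a-only regions named here lay below the maximum folds of the Sin3a lists, 27.3 in the Sin3a line and 32.3 in the Nanog + Sin3a line. The top of these, on chromosome 7 at 91233517-91234079, had folds of 9.01 in the Sin3a line and 7.83 in the Nanog + Sin3a line, and the next, on chromosome 5 at 116181248-116181619, had 9.33 and 10.6.

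Which Sin3a sites the lines shared was asked first. Of the 17168 Sin3a peaks of the Sin3a line, 84.2% (83.7 to 84.8%) overlapped a Sin3a peak of the Nanog + Sin3a line by at least 1 base, and 80.4% (79.8 to 81.0%) of the 18231 peaks of the Nanog + Sin3a line overlapped one of the Sin3a line. Rotating the peaks along each chromosome 1000 times gave a mean overlap of 0.927% (SD 0.105 over rotations). Peaks absent from the other line were mostly weak: 3433 of the 3434 peaks in the strongest 20% of the Sin3a line's list overlapped, and 55.3% of those in the weakest 20%. None of the 2864 peaks with a −log10 q of 25 or more in the Sin3a line lacked a counterpart, and 1 of 2250 did in the Nanog + Sin3a line. The strongest region found only in the Sin3a list of the Sin3a line, on chromosome 5 at 31040614-31041053, had a −log10 q of 21.0 and a fold of 6.64. The strongest found only in the Sin3a list of the Nanog + Sin3a line, on chromosome 15 at 53176941-53177513, had a −log10 q of 15.0 and a fold of 6.04.

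Nanog sites were compared between the line with Nanog alone and the line with added Sin3a. Of the FLAG peaks of the Nanog line, 74.2% (73.8 to 74.6%) overlapped a FLAG peak of the Nanog + Sin3a line, and 79.7% (79.3 to 80.1%) of the peaks of the Nanog + Sin3a line overlapped one of the Nanog line, against a rotated mean of 1.35% and 1.43%. In the strongest 20% of the Nanog line's list 7694 of 7697 peaks overlapped, and in the weakest 20% the share was 38.7%. In the Nanog + Sin3a line the corresponding shares were 96.7% and 59.8%. At a −log10 q of 25 or more, 155 of 5615 FLAG peaks of the Nanog + Sin3a line had no counterpart in the Nanog line, and 1 of 6637 peaks of the Nanog line had none in the Nanog + Sin3a line. This threshold was chosen after the data were seen, and the count was 271 at 20 and 95 at 30. The strongest of the 155 lay on chromosome 8 at 60202544-60202941, with a fold of 17.4, a −log10 q of 90.8 and 141 fragments over the summit (119 to 166). The next were on chromosome 6 at 54038232-54038674 (fold 14.9), within a segment where both lists of this line held more peaks than those of the single-transgene lines, on chromosome 9 at 113579846-113580284 (fold 14.5) and on chromosome 15 at 80677465-80677991 (fold 14.4). The strongest region found only in the FLAG list of the Nanog line, on chromosome 4 at 88286864-88287225, had a fold of 7.97 and a −log10 q of 25.3.

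Most Sin3a peaks lay at FLAG-Nanog peaks, and fewer than 50% of FLAG-Nanog peaks lay at Sin3a peaks. In the Nanog + Sin3a line, 80.3% of Sin3a peaks (79.8 to 80.9%) overlapped a FLAG peak and 42.2% of FLAG peaks (41.7 to 42.7%) overlapped a Sin3a peak, which was 51.7 and 53.5 times the rotated mean. Across the single-transgene lines, 88.5% of the Sin3a peaks of the Sin3a line (88.0 to 89.0%) overlapped a FLAG peak of the Nanog line, and 41.8% of those FLAG peaks (41.3 to 42.2%) overlapped a Sin3a peak, 52.1 and 53.3 times the rotated mean. The percentage was lower among the top 2000 peaks of each list, and its ratio to the rotated mean higher. There 12.2% of Sin3a peaks overlapped a FLAG peak in the Nanog + Sin3a line, 71.8 times the rotated mean, and 18.8% did so across the single-transgene lines, 112 times, whereas 71.5% of the top Sin3a peaks and 66.8% of the top FLAG peaks were shared with the other list of the same antibody.

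The share of Sin3a peaks at FLAG peaks was lower in the Nanog + Sin3a line than across the single-transgene lines, a difference of -8.16 points (-8.91 to -7.41). Most of this difference went with the FLAG list. The Sin3a peaks of the Nanog + Sin3a line overlapped the FLAG list of the Nanog line at 87.3%, a difference of -6.99 points (-7.48 to -6.50) between the FLAG lists, and the Sin3a peaks of the Sin3a line differed by -6.90 points (-7.39 to -6.42) between the same FLAG lists. In each of these differences the same Sin3a peaks were scored against both FLAG lists, and the intervals are for matched shares. Exchanging the Sin3a list moved the overlap by -1.17 points with the Nanog line's FLAG list and by -1.26 with that of the Nanog + Sin3a line. For FLAG peaks the difference was 0.47 points with every peak (-0.24 to 1.17), an interval that includes 0, and -8.36 points with the top 17168 peaks of each list.

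Peaks that overlapped a peak of the other antibody, called co-occupied here, were stronger than the other peaks of the same list. For the Nanog + Sin3a line, the other antibody's list was that of the same line. For the Sin3a and Nanog lines it was that of the other single-transgene line, so binding of both proteins in the same cells was not shown. In the Nanog + Sin3a line the lists came from separate precipitations, so it was not shown there either. The median fold of co-occupied Sin3a peaks was 4.94 in the Sin3a line, against 3.65 for the rest, a ratio of 1.35, and the ratio was 1.30 in the Nanog + Sin3a line. For FLAG peaks the ratio was 1.39 in the Nanog line (5.98 against 4.30) and 1.23 in the Nanog + Sin3a line (5.38 against 4.36). In each list the co-occupied median exceeded those of all 10000 random sets of the same number of peaks. These sets were not matched for width. Overlap by 1 shared base favours wide peaks, so strength was not separated from width. Co-occupied peaks were also wider, at 541 against 295 bp for Sin3a in the Sin3a line and 543 against 288 bp for FLAG in the Nanog line.

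Overlap with the other antibody was higher in the strongest 20% of each list than in its weakest 20%. The strongest 20% of the Sin3a peaks overlapped FLAG peaks at 99.2% in the single-transgene comparison and 97.6% in the Nanog + Sin3a line, and the weakest 20% at 73.5% and 63.5%. FLAG peaks of the Nanog line overlapped Sin3a peaks of the Sin3a line at 69.6% in the strongest and 21.0% in the weakest 20%. In the Nanog + Sin3a line the corresponding shares were 57.3% and 28.7%, and the strongest 5% of the FLAG peaks overlapped Sin3a at 50.6% (48.3 to 52.9%), against 58.6% (56.3 to 60.8%) in the 5% that followed.

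**Figure D2:**
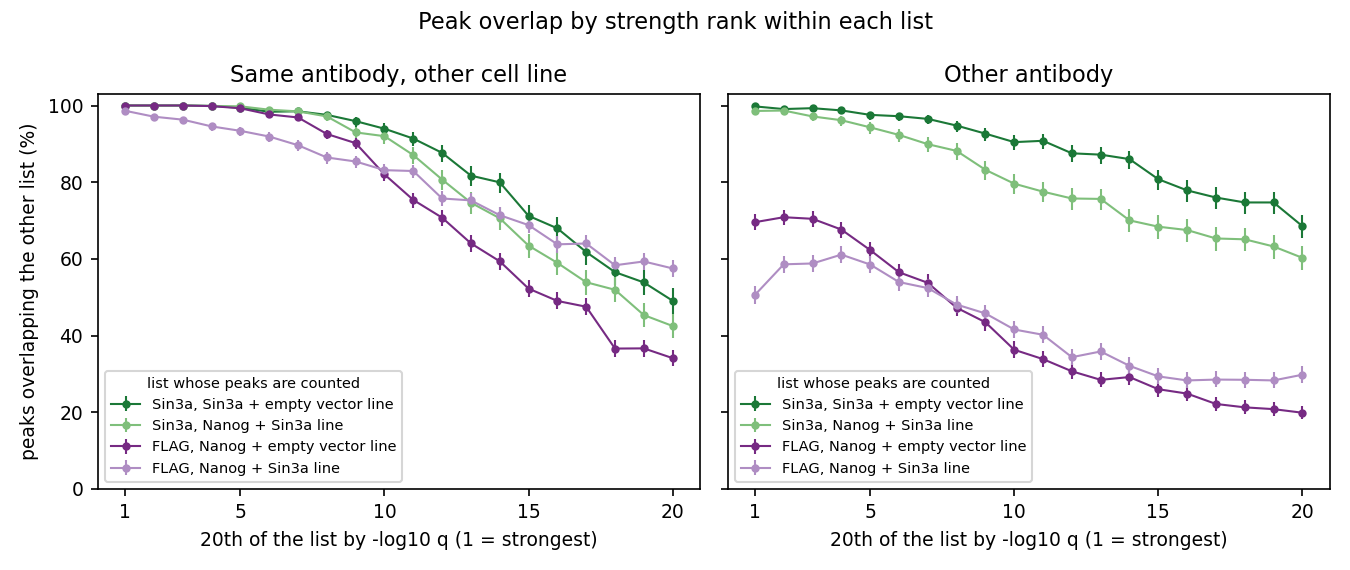
Percentage of peaks that overlap the other list (vertical axis) for each of 20 equal parts of a list ranked by −log10 q (horizontal axis, 1 is the strongest), for the other line's list of the same antibody (left) and for the other antibody (right: the list of the same line for Nanog + Sin3a, and the other single-transgene line's list otherwise); points are shares and bars 95% Wilson intervals. Each curve ends lower than it starts, and the FLAG curve of the Nanog + Sin3a line starts at 50.6% in the right panel.

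At peaks that overlapped one to one, summits of Sin3a and Nanog lay farther apart than summits of 1 antibody in different lines. The overlap itself limits these distances to about the widths of the peaks, so they were compared only with each other. The sets of pairs were not matched for width, so distance was not separated from width. Merged regions with FLAG peaks of both lines and no Sin3a peak had a median width of 394 bp, against 894 bp for regions of all 4 lists. The median distance between Sin3a and FLAG summits was 82 bp in the Nanog + Sin3a line (12359 pairs) and 75 bp across the single-transgene lines (12999 pairs). It was 51 bp between the Sin3a lists and 37 bp between the FLAG lists. Summits lay within 100 bp of each other at 57.0% (56.1 to 57.8%) of Sin3a and FLAG pairs in the Nanog + Sin3a line, at 60.4% (59.6 to 61.3%) across the single-transgene lines, at 72.0% between the Sin3a lists and at 83.4% between the FLAG lists.

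The X chromosome held few peaks of either protein in these female cells. Its share of the peaks was 1.27% (1.11 to 1.45%) for Sin3a in the Sin3a line, 1.19% (1.04 to 1.36%) for Sin3a in the Nanog + Sin3a line and 1.60% (1.48 to 1.74%) for FLAG in the Nanog + Sin3a line. In the FLAG list of the Nanog line, 579 of 38485 peaks lay on the X chromosome (1.39 to 1.63%). Per Mb, the X chromosome carried 0.191 and 0.179 times the autosomal density for Sin3a in the Sin3a and Nanog + Sin3a lines, and 0.227 and 0.241 times for FLAG in the Nanog and Nanog + Sin3a lines. Among peaks with a −log10 q of 10 or more, the shares for Sin3a were lower, at 0.588% in the Sin3a line and 0.499% in the Nanog + Sin3a line. Those for FLAG were lower too, at 1.14% in the Nanog line and 1.25% in the Nanog + Sin3a line. Densities are per Mb of the full mm9 length and were not corrected for mappable sequence or copy number. The cause of the low density was not tested.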

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

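No paired analysis was possible because each group has 1 peak list without values per replicate, and for the same reason leaving out a replicate was not possible. Promoter windows of 1, 2 and 5 kb and the gene lists were not run, since the gene table used here is of another build. All values here are from alternatives set before the data were examined, except those on strong FLAG peaks, which were chosen after the data were seen. The cause of these shifts was not tested, beyond the fewer peaks that stricter settings leave.

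Overlap stayed above the rotated mean under each alternative compared with it, and rotation was not run with 50% of the shorter peak or with summits within 200 bp. Main overlaps were 84.2% (Sin3a between lines), 74.2% (FLAG between lines), 80.3% (Sin3a at FLAG, Nanog + Sin3a line) and 88.5% (Sin3a at FLAG, single-transgene lines). In that order they were 82.9, 73.0, 77.9 and 86.8% with 50% of the shorter peak, and 72.1, 68.2, 61.2 and 70.4% with summits within 200 bp. At a −log10 q of 5 or more they were 83.3, 73.5, 77.9 and 87.5%, and at 10 or more 82.1, 73.1, 68.0 and 79.7%. The top 17168 peaks gave 82.0% for Sin3a between lines, 53.6% and 61.7% for Sin3a at FLAG, and the top 36286 gave 76.7% for FLAG between lines. The top 2000 peaks gave 71.5, 66.8, 12.2 and 18.8%. Peaks with a −log10 q of 10 or more against every peak of the other line gave 98.2% for Sin3a and 96.5% for FLAG. Without regions of all 4 lists, Sin3a at FLAG in the Nanog + Sin3a line was 38.8%. This setting leaves out regions because both antibodies have a peak there, so the lower share follows from its construction, and the ratio to the rotated overlap was 58.7 against 51.7.

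The difference of Sin3a peaks between lines (-8.16 points) kept its sign, at -9.17 with summits, -9.57 and -11.7 at a −log10 q of 5 and 10, and -6.55 with the top 2000. That of FLAG peaks (0.47) was 0.15 with 50% of the shorter peak and turned negative elsewhere, at -0.67 with summits, -1.46 and -4.25 at a −log10 q of 5 and 10, -8.36 with the top 17168 and -6.60 with the top 2000. Ratios of median strength (Sin3a in the Sin3a and Nanog + Sin3a lines, FLAG in the Nanog and Nanog + Sin3a lines) were 2.13, 1.86, 2.00 and 1.67 with −log10 q, and 1.18, 1.15, 1.18 and 1.08 at a −log10 q of 10 or more. The X shares, in the same order, were 0.588, 0.499, 1.14 and 1.25% at a −log10 q of 10 or more, and 0.953% for Sin3a in the Nanog + Sin3a line at 5 or more. Strong FLAG peaks found only in the Nanog + Sin3a line numbered 155, with 271 at a −log10 q of 20, 95 at 30, 342 by summits within 200 bp, 149 by peaks within 1 kb and 154 without the segment of chromosome 6. In the other direction of each overlap, 26 alternatives moved the share beyond its interval and 1 did not. Of the ratios to the rotated overlap, 26 moved by over 10% and 14 did not, from 51.7 to 492.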

Other observations

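The tests in this part were chosen after the patterns were seen, except the overlaps of the top 2000 peaks, which were planned and only their limits set later. The limits for depth and for peak edges were set before their own values were computed, and those of every other test after related values had been seen.

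Peaks of both proteins were clustered along the chromosomes. Another peak of the same list lay within 10000 bp of 56.1% and 60.8% of Sin3a peaks in the Sin3a and Nanog + Sin3a lines, and of 68.7% and 63.0% of FLAG peaks in the Nanog and Nanog + Sin3a lines. Random placement gave at most 14.9, 15.9, 28.7 and 27.2% in 100 draws. In all 4 lists the fullest cluster lay at one place on chromosome 13: at 23580604-23678646 with 38 FLAG peaks in the Nanog line, at 23580616-23690177 with 41 in the Nanog + Sin3a line, and at 23608941-23677938 and 23592690-23677911 with 23 Sin3a peaks each in the Sin3a and Nanog + Sin3a lines.

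The 155 strong FLAG peaks found only in the Nanog + Sin3a line had a median fold of 9.06 and lay on 20 chromosomes, with at most 19 on 1 of them. Peak edges that just miss each other are argued against, since 3.87% lay within 1 kb of a FLAG peak of the Nanog line, and so are extra copies of a few segments, since 11.6% lay in the 5 fullest windows of 10 Mb. Sites that any antibody enriches in this line are argued against too: 0 held a Sin3a peak of the same line, which allows up to 1.94%. The share was 57.5% among the 5460 strong FLAG peaks shared with the Nanog line, but this is not a base rate. Absence from the Nanog line's FLAG list itself selects against Sin3a sites, since 87.3% of this line's Sin3a peaks overlapped that list. At a −log10 q of 10 or more, 1287 of the 1314 FLAG peaks absent from it were in no other list. Depth and the calling threshold alone are argued against: at equal ChIP strength, 1.6e-07 of the 155 peaks would be missed in the Nanog line's list. The median relative strength at 4943 shared strong peaks was 1.02. Depth together with a lower strength at these sites stays open, since its value lay between the limits set. The number missed would be 31.4 if the Nanog line's strength at them were as low as at the weakest 1% of shared peaks. That strength was 0.342 times that of the Nanog + Sin3a line. It comes only from peaks called in both lists, which leaves out lower strengths, so 31.4 is not an upper limit. A difference that goes with added Sin3a, and a difference between 2 separately made lines, cannot be told apart with 1 line per condition, and neither was tested.

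Over 50 to 56 Mb of chromosome 6, both lists of the Nanog + Sin3a line held more peaks: 84 Sin3a peaks against 43 in the Sin3a line, and 196 FLAG peaks against 95 in the Nanog line, whereas the 6 Mb before held 22 against 23 and 39 against 52, and the 6 Mb after 15 against 15 and 24 against 20. The excess was not confined to the 2 windows of 1 Mb that gained most. Without them, the share of peaks was still 1.66 times as high for Sin3a (1.01 to 2.71, so only just above 1) and 2.14 times for FLAG (1.52 to 3.03). These intervals take peaks as independent, although peaks were clustered, and the segment was chosen from the excess itself. The test therefore cannot decide on gains at a few sites. Extra copies of the segment in this line and a regional gain of both proteins stay open. The ratio of at least 1.84 over the whole segment was known when the segment was chosen and would follow from either. The series holds 1 input and not an input for each line, and it was not analysed here. Chance along the genome could not be excluded by the limit set: 16 of 1000 rotations of the Sin3a counts against the FLAG counts gave a window as high with both antibodies, between the limits of 1% and 5%. The borders were drawn around the excess, which favours the pattern in these tests.

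Sites that rank highest with any antibody may contribute to the overlap of Nanog and Sin3a peaks. Of the top 2000 Sin3a peaks, 18.8% lay at top FLAG peaks across the single-transgene lines and 12.2% in the Nanog + Sin3a line. Between lists of the same antibody, 71.5% of the top Sin3a peaks of the Sin3a line were shared. For the top FLAG peaks of the Nanog line the share was 66.8%. These values argue only against the same sites ranking highest with both antibodies. A site that any antibody enriches need not rank among the top 2000 of each list, so they cannot decide on such sites. Of the strongest 3434 Sin3a peaks of the Sin3a line, 99.2% overlapped a FLAG peak of any rank in the Nanog line. At a −log10 q of 10 or more in both lists, 79.7% of the Sin3a line's peaks lay at FLAG peaks of the Nanog line. The share was 82.1% with the Sin3a list of the Nanog + Sin3a line. These lists were of unlike size, with 18346 FLAG peaks and 8616 Sin3a peaks at that limit. With the top 17168 peaks of each list the shares were 61.7% and 82.0%. Sites that any antibody enriches stay open as a source of the overlap, because the IgG sample was not analysed here. No biological explanation was tested.

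Elsewhere on chromosome 6, the stretch from 120 to 130 Mb held 297 Sin3a peaks in the Nanog + Sin3a line and 146 in the Sin3a line, beside 402 and 460 FLAG peaks in the Nanog + Sin3a and Nanog lines. From 28 to 32 Mb, the Sin3a lists held 34 and 55 peaks in the Nanog + Sin3a and Sin3a lines, beside 66 and 78 FLAG peaks in the Nanog + Sin3a and Nanog lines. The borders of both stretches were set after the data were seen, and neither stretch was tested against chance. Chromosome 14 carried 2.59 and 2.92 Sin3a peaks per Mb in the Sin3a and Nanog + Sin3a lines, against 6.86 and 7.29 over the autosomes. FLAG peaks were sparse there too, at 6.33 and 6.50 per Mb in the Nanog and Nanog + Sin3a lines, against 15.3 and 14.4.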
